A study of Mus musculus with 20 samples.

How the data were processed

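RNA was measured in 20 libraries of sorted mouse kidney cells, which the labels place in 15 groups by component and age. Cells were dissociated and isolated by fluorescence-activated cell sorting, either by a green fluorescent reporter (Hoxb7, Six2, Crym, Mafb, Meis1 or Tie2) or, for proximal tubules, by a fluorescently labelled lectin (LTA), per the labels' protocols. Embryonic and neonatal tissue was dissociated with trypsin and adult tissue with collagenase and then trypsin, per the labels' protocols. Total RNA was amplified with the NuGEN Ovation RNA-Seq System v2 before Nextera library preparation, per the labels' protocols.

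The deposited values are RPKM (reads per kilobase of gene, scaled to sequencing depth), computed by the authors on a linear scale in 1 table of 37406 genes and 20 columns, 1 per library. TopHat 1.4.1, DESeq and the mouse genome build mm9 are named in the submitters' processing notes, which give no roles. The read counter, the gene annotation, the handling of reads that map to several places and any further scaling are not given in the sources used here. Coordinates are those of the deposited table, on build mm9, counted as the table gives them. In the table, 308 symbols have 2 or more entries, 623 in all, and these were kept apart by their gene identifier.

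Raw counts were not used here. Low values of a gene step between libraries by fixed factors, and from the value of 1 read the depth was estimated at 2.61 to 40.8 M reads per library (M stands for 1e6). Many values lie between the steps, so that no test on counts was made and the depth is approximate. The RPKM columns summed to between 267008 and 406233. Exon lengths came from a mouse annotation of another build and were used for lengths only.

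Statistics were computed on log2(RPKM + 1) with limma 3.58.1 in R 4.3.3, so that a fold change is on that scale and understates the change of weakly expressed genes. One model with a mean per group held the 9 libraries of the 4 E15.5 groups that have replicates (collecting duct 3, ureter 2, podocyte 2, proximal tubule 2), with 5 residual degrees of freedom and moderated variances with a trend on the mean. Genes with at least 1 RPKM in at least 2 of the 9 libraries were tested, 14194 in all. Each compartment was compared with the average of the other 3 group means, and collecting ducts with ureters. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1, in a 2-sided test. No replicate block entered this model.

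Of 24 gene lists of cell type markers and cell processes, those with at least 5 measured genes were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists within a comparison, and again with an estimated correlation. With the preset correlation 60 of the 120 list tests passed, and with the estimated correlation 0 did, so that the adjusted p from the estimated correlation is given beside each list.

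Where a group has 1 library no test was made. A gene was then counted as differing at an absolute log2 ratio of at least 2 with at least 10 RPKM on the higher side, and, against 2 libraries, at the same distance from the nearer one. The median log2 ratio of a list was placed as a percentile among 10000 random lists of the same size matched on mean expression in 20 bins, which describes those libraries only.

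The gene lists, the comparisons, the thresholds, the first set of alternatives and the rule for named genes were fixed before the data were examined. Which lists each comparison is about was assigned later, with the values in hand, as were the alternatives with a term for a library family or without the libraries of 1 family. Named genes were, in each tested comparison, the 10 with the largest fold change in each direction among those past the threshold whose libraries did not overlap those they were compared with and whose higher group mean was at least 10 RPKM. To these were added up to 6 members of each list the comparison is about, by adjusted p or by size of the ratio, members that went against their list, and the reporter and sex-linked genes. In comparisons without a test the 10 largest ratios in each direction were named. Predicted genes, clone names, symbols with several entries, microRNAs, small nucleolar RNAs, ribosomal pseudogenes and ribosomal RNAs were measured but not named. A few genes outside the rule (Gm20594, Rpl41, Mir682) are used as technical descriptions of libraries and were chosen after their values were seen.

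The test was checked on simulated data with 200 changed genes. Of the genes changed by 1.5 log2 units, 66% were recovered for podocytes, 65% for proximal tubules, 74% for collecting ducts, 68% for ureters and 54% for collecting ducts against ureters, and of those changed by 3 units 86%, 87%, 90%, 89% and 87%. False calls numbered 7, 10, 2, 7 and 9 of 13557, 13545, 13527, 13536 and 13547 genes. Camera found the 1 shifted list and called 0 of 23 unshifted lists. The list percentile was 100 for the shifted list, and 0 of 17 unshifted lists fell outside the central 95% of random lists. The simulated noise was independent between genes and between libraries. These checks therefore cannot show false calls that come from correlated genes or libraries, and the estimated correlation within a list reached 0.909 for endothelium.

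Alternatives were other pseudocounts, filters and ratio thresholds, median-ratio scaling, quantile normalization and variances without a trend. Further ones were a replicate block, 2-group models, a requirement to pass against each other group separately, and leaving out each replicate in turn. In the 2-group models the other 3 compartments shared 1 mean, so that differences between them entered the residual variance. For collecting ducts against ureters the 2-group model held only those groups. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest.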

Results

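Transcript levels were measured by RNA sequencing in 20 libraries of sorted cells from the developing and adult mouse kidney, in a series that serves as an atlas of kidney components. At embryonic day 15.5 (E15.5), collecting ducts had 3 libraries, and ureters, podocytes and proximal tubules had 2 each. The other 11 groups had 1 library each: the E11.5 ureteric tip and trunk, the E12.5 and P1 cap mesenchyme, the P4 renal vesicle, E15.5 mesangial and endothelial cells, and adult proximal tubules, podocytes, mesangial cells and endothelial cells. Values are RPKM in the deposited table, and positions are on mouse build mm9. The approximate depth ran from 2.61 M reads in the P4 library to 40.8 M reads in the adult podocyte library, with 3.88 M reads in the P1 library and 4.29 M reads in proximal tubule 3. Between 10735 and 13828 genes per library reached 1 RPKM. Most libraries were made from pooled kidneys, and nothing ties replicates to separate animals or litters throughout, so that p-values measure the spread between these libraries, which can be technical.

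Genes that drive the sorting reporters were read first. Mafb stood at 461 and 468 RPKM in the E15.5 podocyte libraries and 227 RPKM in the adult one, and at no more than 48.7 RPKM elsewhere. Tek, the receptor gene also called Tie2, stood at 161 RPKM in E15.5 and 216 RPKM in adult endothelial cells, but also at 56.2 and 30.6 RPKM in the ureters and 46.7 RPKM in adult mesangial cells. Hoxb7 was at 92.3, 112 and 121 RPKM in the collecting ducts, 50.7 and 42.0 RPKM in the ureters, 48.3 RPKM in the ureteric tip and 61.0 RPKM in the trunk, and reached 51.2 RPKM in the P4 library. Six2 was at 175 RPKM in the E12.5 and 199.6 RPKM in the P1 cap mesenchyme, but also at 76.1 and 52.9 RPKM in the Hoxb7-sorted ureteric tip and trunk and 60.9 RPKM in E15.5 mesangial cells. Crym was at 343 RPKM in the P1 library and at 4.30 RPKM in the P4 library, although both were sorted by a Crym reporter, and at 202 RPKM in the Six2-sorted E12.5 cap mesenchyme. Meis1 was at 21.7 RPKM in E15.5 and 9.12 RPKM in adult mesangial cells. It was also at 19.4 RPKM in the P1 and 18.5 RPKM in the E12.5 cap mesenchyme and at 12.3 and 14.5 RPKM in the E15.5 proximal tubules.

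Replicates were compared before they were averaged, and no columns held identical values. Collecting duct 2 and 3 differed at least 4-fold in 3 genes, while collecting duct 1 differed from them in 130 and 113 genes. Such differences numbered 103 between the ureters, 1 between the podocyte libraries and 22 between the proximal tubule libraries. Gm20594, used here as a technical description and chosen after its values were seen, was at 1840 RPKM in collecting duct 1 and 2583 RPKM in ureter 1, against 7579 to 17436 RPKM in the other 7 libraries of these groups. The endothelium list averaged 4.06 log2 units in collecting duct 1 and 1.45 and 1.70 in collecting duct 2 and 3.

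**Figure D1:**
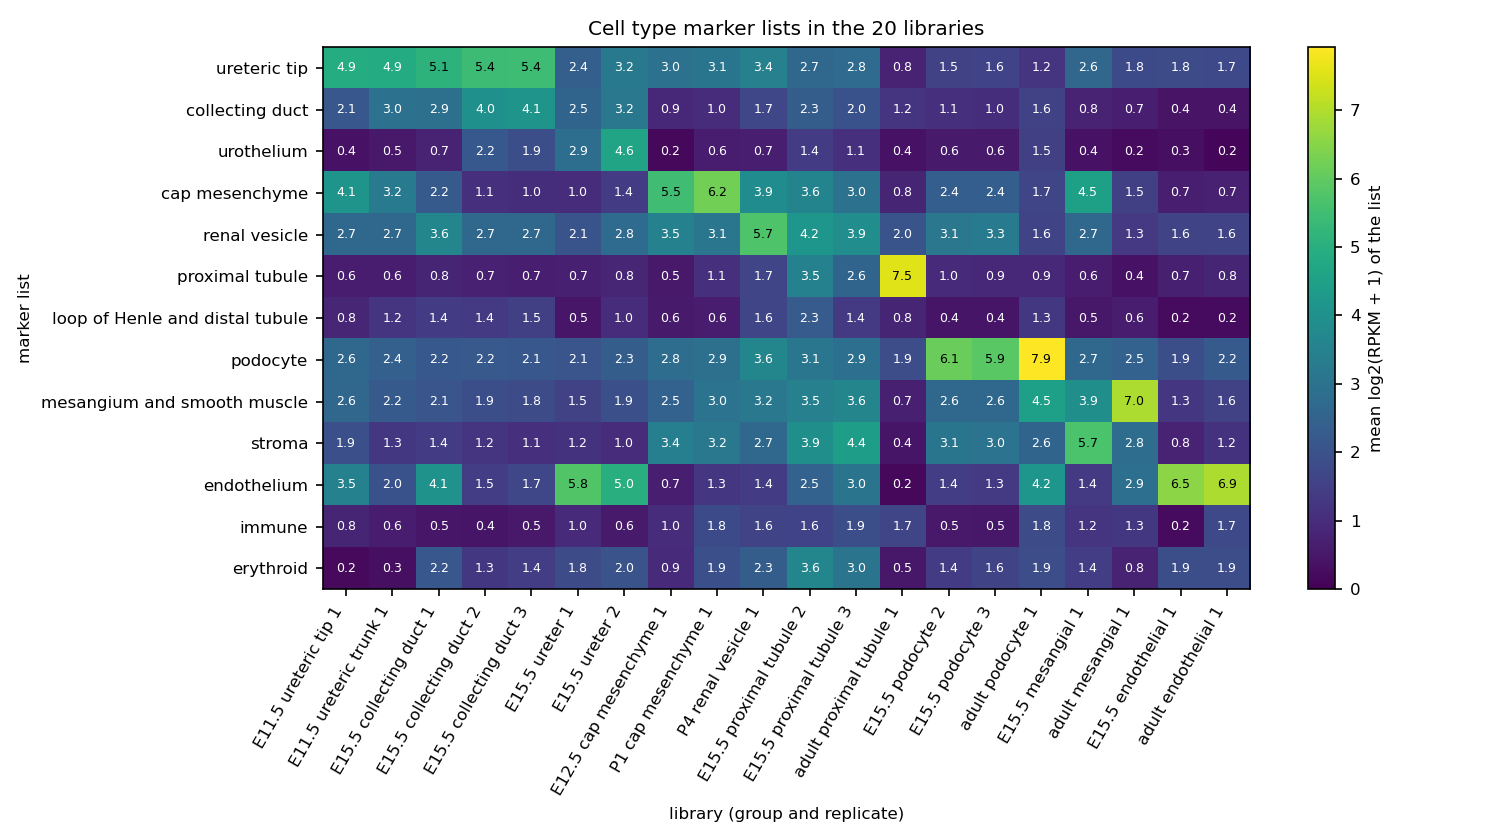
Mean log2(RPKM + 1) of the 13 cell type lists in each of the 20 libraries, with lists as rows of the grid, libraries as columns and color for the mean. The podocyte list stands at 6.11 and 5.89 in the E15.5 podocyte libraries and 7.92 in the adult one, and the endothelium list at 5.76 and 4.98 in the ureters beside 6.55 in E15.5 endothelial cells.

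Podocytes, the filtering epithelium of the glomerulus, were set apart at E15.5 by markers of the lineage, of which 25 of 28 rose. Nphs2, which encodes podocin of the slit diaphragm (chromosome 1: 158240866 to 158258166), stood at 291 ± 59.5 RPKM (SD, n = 2) and rose by 7.64 log2 units (SE 0.24, adjusted p = 9.29e-07, limma) against the average of collecting ducts, ureters and proximal tubules. Wt1, a transcription factor that podocytes need (chromosome 2: 104966686 to 105013771), was at 414 ± 17.2 RPKM and 6.76 log2 units higher (SE 0.30, adjusted p = 2.77e-06). The largest difference was in Pcp4, a calmodulin-binding protein gene (chromosome 16: 96689213 to 96747400), at 994 ± 97.1 RPKM and 9.31 log2 units higher (SE 0.36, adjusted p = 1.57e-06). Cdh1, which encodes E-cadherin of epithelial junctions, was lower, at 3.25 ± 0.508 RPKM against 134 ± 30.9 RPKM in collecting ducts (n = 3), a log2 fold change of -4.91.

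In podocytes 949 of 14194 genes were higher and 1192 lower, in both directions at an adjusted p under 0.05 and at least 2-fold. R3hdml, Mafb, Ntng2, Tcf21, Ptpro, Gja3 and Cxx1c rose by 8.47, 6.59, 6.52, 6.27, 5.92, 5.56 and 5.53 log2 units. Of 28 podocyte markers 25 rose, also 25 adjusted over the list alone (camera adjusted p = 6.38e-29, adjusted p = 0.0971 with an estimated correlation), among them Foxc2 at 4.98, Synpo at 4.92 and Lmx1b at 4.28 log2 units. The genes that fell included Cldn6, Cldn8, Cldn7 and Cldn4, which encode claudins, at -4.76, -4.62, -4.41 and -4.32, and Mal2 at -4.53. Aplnr, a receptor gene also high in endothelium, fell by 4.89. Of the glomerular basement membrane list 3 of 13 genes rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.00766, adjusted p = 0.436 with an estimated correlation). Its risers were the collagen chains Col4a3 (2.01) and Col4a4 (1.60) and Nid1 (2.16). Hspg2 (-1.64) and Lama1 (-1.13) fell, and Col4a2 (0.94) did not reach the fold threshold, which it reached without collecting duct 1 (1.01) or proximal tubule 2 (1.04). The list no longer passed without podocyte 2 (adjusted p = 0.170) or podocyte 3 (0.0873).

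Lists of the ureteric tree were lower in podocytes: 13 of 15 ureteric tip genes fell, 13 adjusted over the list alone (adjusted p = 4.89e-09, adjusted p = 0.136 with an estimated correlation). Of 18 collecting duct genes 13 fell, 14 adjusted over the list alone (adjusted p = 2.6e-07, adjusted p = 0.436 with an estimated correlation). Of 15 urothelium genes 9 fell, also 9 over the list alone (adjusted p = 0.00101, adjusted p = 0.544 with an estimated correlation). Of 33 proximal tubule genes 9 fell and 2 rose, the same over the list alone (adjusted p = 0.00482, adjusted p = 0.577 with an estimated correlation), and this list no longer passed without proximal tubule 2 (adjusted p = 0.356). The renal vesicle list, with 3 of 15 genes higher and 1 lower, did not pass (mean 0.06, median -0.57, adjusted p = 0.718). Of 8 loop of Henle genes 3 fell, 5 over the list alone (adjusted p = 0.00437, adjusted p = 0.443 with an estimated correlation). Of 19 endothelium genes 14 fell and 1 rose, 17 and 1 adjusted over the list alone (adjusted p = 7.37e-05, adjusted p = 0.544 with an estimated correlation). The endothelium list averaged 1.39 log2 units in podocytes, 2.40 in collecting ducts, 2.76 in proximal tubules and 5.37 in ureters. Its fall in podocytes thus rests mostly on the high ureter libraries. Of 26 cell cycle genes 7 fell, also 7 over the list alone (adjusted p = 2.33e-07, adjusted p = 0.259 with an estimated correlation). Of 10 fetal RNA-binding and growth genes 4 fell, also 4 over the list alone (adjusted p = 0.00101, adjusted p = 0.136 with an estimated correlation). Of 16 immediate early and heat shock genes 5 fell and 1 rose, 6 and 1 over the list alone (adjusted p = 0.0390, adjusted p = 0.577 with an estimated correlation). That list no longer passed without podocyte 3 (adjusted p = 0.0717), proximal tubule 2 (0.0766) or ureter 2 (0.0909). Of 15 stroma genes 8 rose and 1 fell, the same over the list alone (adjusted p = 0.000761, adjusted p = 0.436 with an estimated correlation). The stroma list averaged 3.04 log2 units in podocytes, above 1.23 in collecting ducts and 1.08 in ureters but below 4.18 in proximal tubules. The mesangium list did not pass (adjusted p = 0.104), but did without proximal tubule 3 (0.0417). Without podocyte 2 the counts were 505 higher and 466 lower, and without podocyte 3 they were 569 and 542. Several calls ended without 1 library: Krt19 (-4.56) without podocyte 2 (adjusted p = 0.0689), Fabp4 (-4.39) without podocyte 2 (0.0503) or 3 (0.0571), Hspg2 without podocyte 3 (0.0540), Nid1 without podocyte 2 (0.156), podocyte 3 (0.149) or proximal tubule 2 (0.0524), and Lama1 without podocyte 2 (0.0918), podocyte 3 (0.119) or ureter 2, where its fold change was -0.96.

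Proximal tubules, which reclaim most of the filtrate, were set apart at E15.5 by markers of the lineage, of which 26 of 33 rose. Hnf4a, a transcription factor of the lineage (chromosome 2: 163332674 to 163398643), stood at 97.2 ± 25.5 RPKM (SD, n = 2) and rose by 5.41 log2 units (SE 0.26, adjusted p = 3.75e-05, limma). Lrp2, the endocytic receptor megalin (chromosome 2: 69262392 to 69424124), was at 69.6 ± 22.9 RPKM and 4.18 log2 units higher (SE 0.26, adjusted p = 5.4e-05). Slc34a1, a sodium-phosphate cotransporter gene (chromosome 13: 55501009 to 55516056), was at 52.2 ± 43.2 RPKM and 5.12 log2 units higher (SE 0.43, adjusted p = 0.000203). Aldob, of fructose metabolism, had the largest change, 6.17 log2 units (SE 0.36, adjusted p = 4.44e-05), at 135 ± 93.4 RPKM.

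In proximal tubules 815 genes were higher and 315 lower, so that 72.1% of the called genes were higher. With quantile normalization 61.1% were higher and 481 genes lower. Of 33 proximal tubule markers 26 rose, 27 adjusted over the list alone (camera adjusted p = 7.59e-25, adjusted p = 0.161 with an estimated correlation), with Cubn, the partner of megalin, at 4.08 and Cdh6 at 4.18. Cldn2, Dao, Hsd3b4, Tmem27, Mep1a, Cpb2 and Keg1 rose by 5.39, 5.23, 5.04, 5.03, 5.03, 4.99 and 4.95. Lower genes were led by Tmem54 (-3.75), the immediate early gene Fos (-3.52), Tacstd2 (-3.12), Epn3 (-2.44), Efnb2 (-2.39), the keratin gene Krt7 (-2.39), Aldh1a1 (-2.32) and Unc5b (-2.27). Of 16 immediate early and heat shock genes 11 fell, also 11 adjusted over the list alone (adjusted p = 1.71e-09, adjusted p = 0.204 with an estimated correlation), with Ier3 at -2.27, Btg2 at -2.18 and Ier2 at -1.84. The fatty acid oxidation list, with 1 of 19 genes higher, did not pass (adjusted p = 0.0689), but did without proximal tubule 3 (0.0114). The oxidative phosphorylation list did not pass (mean 0.05, median -0.02, adjusted p = 0.530). Of 28 podocyte genes 6 fell and 1 rose, the same over the list alone (adjusted p = 0.000129, adjusted p = 0.321 with an estimated correlation). Of 15 ureteric tip genes 2 fell, 3 over the list alone (adjusted p = 0.0101, adjusted p = 0.321 with an estimated correlation), and of 15 urothelium genes 1, also 1 over the list alone (adjusted p = 0.00904, adjusted p = 0.547 with an estimated correlation). Of 18 collecting duct genes 2 fell and 1 rose, 3 and 1 over the list alone (adjusted p = 0.0333, adjusted p = 0.585 with an estimated correlation). The tip list no longer passed without proximal tubule 2 (adjusted p = 0.146), and the collecting duct list without proximal tubule 2 (0.0642), proximal tubule 3 (0.115) or ureter 2 (0.109).

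Markers of several other cell types were higher in the same libraries. Of the 815 higher genes 202, 24.8%, had still more in the E15.5 mesangial library, against 9.59% of those in podocytes, 7.41% in collecting ducts and 3.09% in ureters. Of all tested genes 43.85% had more in that library than in proximal tubules, 49.1% than in podocytes, 43.8% than in collecting ducts and 45.6% than in ureters. Called genes were chosen for high values in their compartment, so that lower shares among them are built in. Of 15 stroma genes 13 rose, also 13 over the list alone (adjusted p = 4.57e-14, adjusted p = 0.0725 with an estimated correlation). Col1a1, a chain of fibrillar collagen, was at 61.3 ± 11.9 RPKM (n = 2) and 3.41 log2 units higher (SE 0.25, adjusted p = 0.000102), and Dcn, Lum, Col3a1, Col1a2 and Pdgfrb at 4.58, 4.14, 3.55, 2.63 and 2.34. Of 16 mesangium and smooth muscle genes 12 rose, 13 over the list alone (adjusted p = 3e-09, adjusted p = 0.0573 with an estimated correlation). Of 10 immune genes 7 rose, also 7 over the list alone (adjusted p = 4.32e-06, adjusted p = 0.0725 with an estimated correlation). Of 14 cap mesenchyme genes 8 rose, 11 over the list alone (adjusted p = 1.86e-07, adjusted p = 0.321 with an estimated correlation), and of 15 renal vesicle genes 7, 8 over the list alone (adjusted p = 0.000143, adjusted p = 0.321 with an estimated correlation). Of 8 loop of Henle genes 4 rose, 5 over the list alone (adjusted p = 0.000906, adjusted p = 0.321 with an estimated correlation), and this list no longer passed without proximal tubule 2 (adjusted p = 0.146). Of 6 erythroid genes 4 rose, 6 over the list alone (adjusted p = 0.000309, adjusted p = 0.204 with an estimated correlation), with Hba-a1 at 319.6 ± 281 RPKM. Hba-a1 and Hba-a2 are near-identical copies, so that their separate values are uncertain. The cell cycle list of 26 genes passed with a mean of 0.34 (adjusted p = 0.00105, adjusted p = 0.321 with an estimated correlation), with 0 genes past the threshold. It averaged 5.56 log2 units in proximal tubules, 5.64 in collecting ducts, 5.30 in ureters and 4.70 in podocytes, so that its mean rests mostly on low podocytes. The endothelium list did not pass (adjusted p = 0.261), but did, with lower values, without proximal tubule 3 (mean -0.60, adjusted p = 0.0416).

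The proximal tubule counts were 415 higher and 72 lower without proximal tubule 3, and 423 genes were higher without proximal tubule 2. Lower genes numbered 190 without podocyte 2 and 197 without podocyte 3. Without proximal tubule 3 the calls of Fos (adjusted p = 0.0564), Sh2d4a (-2.55 with all libraries, adjusted p = 0.108 without it), Itga3 (-2.30, then 0.0767), Jun (-1.26, then 0.0699) and Fosb (-2.26, then 0.0752) ended. Without proximal tubule 2 those of Hba-a1 (3.61, then 0.0884) and Hba-a2 (3.31, then 0.122) ended.

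Collecting ducts at E15.5, where the ureteric tree branches, carried genes of the branching tip together with genes of the duct. Ret, the receptor tyrosine kinase that drives branching (chromosome 6: 118101766 to 118147762), stood at 53.4 ± 15.3 RPKM (SD, n = 3) and rose by 4.62 log2 units (SE 0.42, adjusted p = 0.000312, limma). Wnt11, a ligand gene of the tip (chromosome 7: 105983622 to 106003257), was at 26.5 ± 2.17 RPKM and 3.93 log2 units higher (SE 0.29, adjusted p = 0.000125). Calb1, a calcium-binding protein gene (chromosome 4: 15808411 to 15833856), was at 338 ± 154 RPKM and 5.94 log2 units higher (SE 0.79, adjusted p = 0.00151). Rprm rose by 5.32 (SE 0.26, adjusted p = 4.05e-05).

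In collecting ducts 621 genes were higher and 752 lower. Each of 15 ureteric tip genes rose, also 15 adjusted over the list alone (camera adjusted p = 5.25e-18, adjusted p = 0.0664 with an estimated correlation). Etv5 and Etv4, transcription factors downstream of Ret, rose by 3.52 and 3.26, Sox8 and Sox9 by 3.21 and 3.14 and Dusp6 by 2.04. Of 18 collecting duct genes 14 rose, 15 over the list alone (adjusted p = 3.79e-10, adjusted p = 0.24 with an estimated correlation), with Wnt9b at 3.34, Gata3 at 3.16, Tfcp2l1 at 2.46, Hoxb7 at 1.95 and the vasopressin receptor gene Avpr2 at 1.47. Slco4c1, Ros1, Krt23, Vsnl1, Aldh1a3 and Mal2 rose by 5.01, 4.79, 4.19, 4.18, 3.99 and 3.94. Of 10 fetal RNA-binding and growth genes 3 rose, also 3 over the list alone (adjusted p = 2.78e-05, adjusted p = 0.0664 with an estimated correlation). The cell cycle list of 26 genes passed with a mean of 0.45 (adjusted p = 6.4e-06, adjusted p = 0.202 with an estimated correlation), with 0 genes past the threshold. It averaged 5.64 log2 units in collecting ducts, 5.56 in proximal tubules, 5.30 in ureters and 4.70 in podocytes. The urothelium list did not pass (adjusted p = 0.555), and in it Elf3 rose by 1.30.

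Genes that fell in collecting ducts included Nid1 (-3.23), Npr3 (-2.96), Mxra8 (-2.95), Sepp1 (-2.91), Bgn (-2.90), Cxx1c (-2.89), Sncaip (-2.87), Pmp22 (-2.76) and Sulf1 (-2.74). Of 28 podocyte genes 16 fell, also 16 over the list alone (adjusted p = 2.62e-16, adjusted p = 0.1 with an estimated correlation). Of 15 stroma genes 10 fell, 11 over the list alone (adjusted p = 1.82e-10, adjusted p = 0.1 with an estimated correlation). Of 33 proximal tubule genes 12 fell, 13 over the list alone (adjusted p = 2.65e-09, adjusted p = 0.311 with an estimated correlation). Of 16 mesangium genes 7 fell and 1 rose, the same over the list alone (adjusted p = 0.000771, adjusted p = 0.1 with an estimated correlation), and of 10 immune genes 5 fell and 1 rose, the same over the list alone (adjusted p = 0.00829, adjusted p = 0.192 with an estimated correlation). Of 14 cap mesenchyme genes 6 fell, also 6 over the list alone (adjusted p = 0.000902, adjusted p = 0.392 with an estimated correlation). Of 12 imprinted growth genes 3 fell, also 3 over the list alone (adjusted p = 0.0244, adjusted p = 0.190 with an estimated correlation), and of 13 glomerular basement membrane genes 3 fell and 1 rose, the same over the list alone (adjusted p = 0.0244, adjusted p = 0.375 with an estimated correlation). The endothelium list passed with a mean of -0.79 (adjusted p = 0.0244, adjusted p = 0.621 with an estimated correlation) and fatty acid oxidation with a mean of -0.24 (adjusted p = 0.0430, adjusted p = 0.384 with an estimated correlation). In collecting ducts the endothelium list averaged 2.40 log2 units, below 5.37 in ureters and 2.76 in proximal tubules but above 1.39 in podocytes. The imprinted list no longer passed without proximal tubule 3 (adjusted p = 0.0870), and the basement membrane list without podocyte 2 (0.0831), podocyte 3 (0.0618) or ureter 1 (0.0548). The endothelium list no longer passed without collecting duct 2 (adjusted p = 0.369), collecting duct 3 (0.200), ureter 1 (0.0915) or proximal tubule 3 (0.0870). Fatty acid oxidation no longer passed without collecting duct 1 (adjusted p = 0.0920), collecting duct 2 (0.0504), ureter 1 (0.0814) or podocyte 3 (0.0576). The call of Krt15 (-1.22) ended without collecting duct 1 (adjusted p = 0.0663), 2 (0.0537) or 3 (0.105) or without podocyte 2 (0.0690) or 3 (0.0647).

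Ureters at E15.5 were set apart by genes of the urothelium and by genes of endothelium. Upk1b, which encodes a uroplakin of the urothelial plaque (chromosome 16: 38773297 to 38800316), stood at 175 ± 177 RPKM (SD, n = 2) and rose by 5.27 log2 units (SE 0.85, adjusted p = 0.00369, limma). Foxa1, a transcription factor of urothelial differentiation (chromosome 12: 58641619 to 58647108), was at 49.2 ± 27.7 RPKM and 4.43 log2 units higher (SE 0.56, adjusted p = 0.00129). Cdh5, the cadherin of endothelial junctions (chromosome 8: 106625525 to 106668402), was at 266 ± 73.4 RPKM and 4.29 log2 units higher (SE 0.74, adjusted p = 0.00488). Wt1 and Tcf21, high in podocytes, fell, with log2 fold changes of -4.67 and -4.56.

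In ureters 1004 genes were higher and 731 lower, and 448 of the higher genes, 44.6%, had still more in the E15.5 endothelial library. That share was 2.85% among genes higher in podocytes, 2.70% in proximal tubules and 4.51% in collecting ducts, and 36.5% of all tested genes had more there than in ureters. Of 15 urothelium genes 12 rose, also 12 adjusted over the list alone (camera adjusted p = 3.81e-09, adjusted p = 0.307 with an estimated correlation), with Upk1a at 3.93, Grhl3 at 3.58, Pparg at 3.32, Trp63 at 3.18 and Krt7 at 2.98. Krt19, Fxyd3, Fam70a and Sfn rose by 5.18, 5.12, 4.73 and 4.35. Of 19 endothelium genes 18 rose, also 18 over the list alone (adjusted p = 4.56e-11, adjusted p = 0.346 with an estimated correlation), with Eng at 3.80, Erg at 3.65, Tie1 at 3.45 and Sox17 at 2.58, beside Aplnr at 4.76 and Robo4 at 4.46. Of 16 immediate early and heat shock genes 14 rose, also 14 over the list alone (adjusted p = 1e-09, adjusted p = 0.193 with an estimated correlation). Of 12 imprinted growth genes 7 rose and 1 fell, the same over the list alone (adjusted p = 0.00248, adjusted p = 0.124 with an estimated correlation). Among these H19 was at 2523 ± 636 RPKM (log2 fold change 1.56), Igf2 at 1814 ± 103 RPKM (1.61) and Mest at 1333 ± 40.6 RPKM (1.50), with Meg3 at 2.06 and Zim1 at 1.27. Cdkn1c, a cyclin-dependent kinase inhibitor gene, went the other way (-1.67), at 50.4 ± 0.833 RPKM against 1456 ± 166 RPKM in podocytes. In the E15.5 endothelial library H19, Igf2 and Mest were at 1827, 1849 and 1911 RPKM, so that their levels are not particular to ureters. The whole imprinted list averaged 5.76 log2 units there and 6.43 in ureters. Of 11 antigen presentation genes 4 rose, 7 over the list alone (adjusted p = 0.000598, adjusted p = 0.124 with an estimated correlation). That list averaged 3.76 log2 units in the E15.5 endothelial library and 3.02 in ureters.

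Genes that fell in ureters included Aldh1a2 (-4.90), Mme (-4.07), Penk (-3.98), Hs3st3b1 (-3.84), Osr2 (-3.69), Lhx1 (-3.56), Dpp4 (-3.52) and Frem1 (-3.49). Of 28 podocyte genes 17 fell, 18 over the list alone (adjusted p = 1.11e-12, adjusted p = 0.124 with an estimated correlation). Of 15 stroma genes 10 fell, also 10 over the list alone (adjusted p = 1.44e-08, adjusted p = 0.124 with an estimated correlation). Of 33 proximal tubule genes 15 fell, also 15 over the list alone, where 3 rose (adjusted p = 3.24e-07, adjusted p = 0.427 with an estimated correlation). Of 16 mesangium genes 9 fell and 2 rose, 9 and 3 over the list alone (adjusted p = 3.21e-05, adjusted p = 0.124 with an estimated correlation). Of 14 cap mesenchyme genes 9 fell and 2 rose, 11 and 2 over the list alone (adjusted p = 0.00138, adjusted p = 0.579 with an estimated correlation). Of 15 renal vesicle genes 7 fell and 1 rose, the same over the list alone (adjusted p = 0.00165, adjusted p = 0.562 with an estimated correlation). The ureteric tip (adjusted p = 0.359) and collecting duct (adjusted p = 0.142) lists did not pass with all libraries. The tip list passed without ureter 2 (adjusted p = 0.0218), and the collecting duct list without collecting duct 2 (0.0315), collecting duct 3 (0.0219) or ureter 1 (0.0296). The call of Cd34 (4.59) ended without ureter 1 (adjusted p = 0.0686), and that of Upk2 (4.51) without ureter 2 (0.126) or proximal tubule 3 (0.0511).

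**Figure D2:**
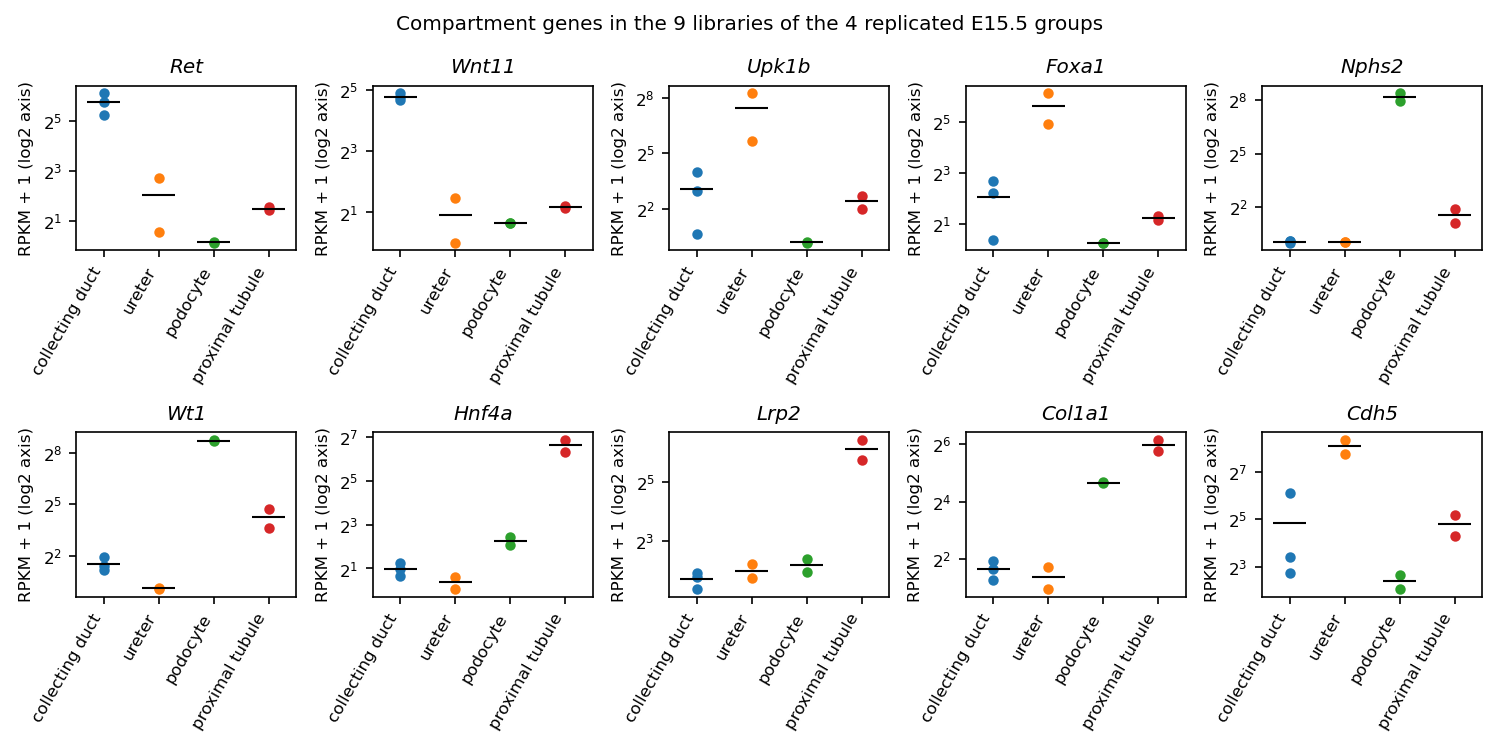
RPKM + 1 on a log2 axis of 10 named genes in the 9 libraries of the 4 replicated E15.5 groups, with 1 point per library and a line at the mean of each group. Ret and Wnt11 are highest in collecting ducts (53.4 and 26.5 RPKM on average), Upk1b and Foxa1 in ureters (175 and 49.2 RPKM), and Cdh5 stands at 266 RPKM in ureters.

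Collecting ducts and ureters, the parts of the ureteric tree inside and outside the kidney, were sorted with the same Hoxb7 reporter and compared directly. Gfra1, which encodes the coreceptor of Ret (chromosome 19: 58311182 to 58529849), stood at 138 ± 27.7 RPKM (SD, n = 3) in collecting ducts and 8.02 ± 7.70 RPKM (n = 2) in ureters, 4.25 log2 units higher (SE 0.49, adjusted p = 0.00246, limma). Ret and Wnt11 were 4.06 (SE 0.54, adjusted p = 0.00403) and 4.04 log2 units higher (SE 0.37, adjusted p = 0.00142). Perp, of desmosomes in stratified epithelia, was 4.60 log2 units lower (log2 fold change -4.60, SE 0.56, adjusted p = 0.0031), as were Foxa1 (-3.75), Grhl3 (-3.53), Pparg (-2.92) and Krt7 (-1.80). Hoxb7 itself was at 108 ± 14.6 RPKM in collecting ducts and 46.3 ± 6.17 RPKM in ureters, a log2 fold change of 1.21.

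Between the 2 compartments 505 genes were higher in collecting ducts and 777 in ureters, and 420 of the latter, 54.1%, had still more in the E15.5 endothelial library, as had 36.5% of all tested genes. Between collecting duct 1 and ureter 1, both low in Gm20594, the log2 differences of Ret, Foxa1 and Cdh5 were 4.68, -4.56 and -2.20, and between collecting duct 2 and 3 and ureter 2 they were 3.21, -3.65 and -4.65, without a test. Of 15 ureteric tip genes 12 were higher in collecting ducts, also 12 adjusted over the list alone (camera adjusted p = 2.34e-15, adjusted p = 0.0515 with an estimated correlation), with Sox8 at 3.26, Etv5 at 2.97, Etv4 at 2.80 and Myb at 2.39. Calb1, Slco4c1, Ros1, Rprm, Vsnl1, Hs3st3a1 and Vldlr were higher by 5.86, 4.72, 4.37, 4.27, 4.11, 3.92 and 3.90. Of 18 collecting duct genes 7 were higher and 1 lower, 9 and 3 over the list alone (adjusted p = 0.00601, adjusted p = 0.678 with an estimated correlation), with Emx2 at 2.77, Wnt9b at 2.41, Hsd11b2 at 1.90 and Avpr2 at 1.32. This list no longer passed without collecting duct 3 (adjusted p = 0.0658). Of 15 urothelium genes 8 were lower, 12 over the list alone (adjusted p = 2.04e-07, adjusted p = 0.485 with an estimated correlation). Of 19 endothelium genes 13 were lower, 19 over the list alone (adjusted p = 1.85e-11, adjusted p = 0.485 with an estimated correlation), with Eng at -3.13, beside Sparcl1 at -4.81 and Gja4 at -3.87.

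Of 12 imprinted growth genes 6 were lower in collecting ducts than in ureters, also 6 over the list alone (adjusted p = 6.98e-05, adjusted p = 0.0515 with an estimated correlation). Of 11 antigen presentation genes 4 were lower, 7 over the list alone (adjusted p = 7.9e-05, adjusted p = 0.0515 with an estimated correlation), and of 16 immediate early genes 7, 8 over the list alone (adjusted p = 0.00019, adjusted p = 0.485 with an estimated correlation). The imprinted and antigen presentation lists averaged 5.76 and 3.76 log2 units in the E15.5 endothelial library, beside 6.43 and 3.02 in ureters. Of 8 loop of Henle genes 2 were higher, 3 over the list alone (adjusted p = 0.0131, adjusted p = 0.517 with an estimated correlation), and this list no longer passed without ureter 1 (adjusted p = 0.0938). The cell cycle list passed with a mean of 0.34 (adjusted p = 0.00179, adjusted p = 0.485 with an estimated correlation). The counts were 305 higher and 408 lower without collecting duct 2, 299 and 345 without collecting duct 3, and 311 and 477 without ureter 1. Calls that ended without 1 library were Upk1b (-4.44) without ureter 2 (adjusted p = 0.105) or collecting duct 3 (0.0556), Robo4 without ureter 1 (0.0706), Trp63 (-2.41) without ureter 2 (0.0620), Krt15 (-2.08) without ureter 2 (0.0660) or collecting duct 3 (0.0532), and Wnt7b (-1.77) without ureter 1 (0.0502), ureter 2 (0.107) or collecting duct 3 (0.0570). Cdh5 (-3.93) ended without collecting duct 2 (0.0514) or 3 (0.0691) or ureter 1 (0.0945) or 2 (0.0564), and Sox17 (-2.60) without ureter 1 (0.0742) or collecting duct 3 (0.0513).

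The following comparisons involve groups of 1 library, so that their differences have no replicate check and no test was made. In proximal tubules the adult library held 28 of 37 proximal tubule markers at higher levels than E15.5. Miox, an enzyme of inositol catabolism (chromosome 15: 89164904 to 89167438), was at 3585 RPKM in the adult and 1.66 ± 0.144 RPKM at E15.5 (SD, n = 2), a log2 ratio of 10.40. Pck1 and G6pc, of gluconeogenesis, had log2 ratios of 8.20 and 8.68, Hpd and Pah, of tyrosine and phenylalanine catabolism, 9.32 and 9.00, and the extracellular glutathione peroxidase gene Gpx3 9.27. Igf2, a fetal growth factor gene, was at 0.103 RPKM in the adult and 613 ± 104 RPKM at E15.5 (-9.11), and H19 (-9.29) and Mest (-8.39) were lower too.

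In proximal tubules 617 genes were higher in the adult and 1001 lower, 22.4% of 7220 genes with at least 10 RPKM. Of 37 proximal tubule genes 28 were higher and 1 lower (median log2 ratio 4.37, percentile 100 among matched random lists), with Akr1c21 at 7.82, Gatm at 7.64 and Fbp1 at 7.60, while Cdh6 went the other way (-3.45). Of 19 fatty acid oxidation genes 10 were higher (median 2.23, percentile 100), with Ehhadh at 6.43, Ppara at 3.93 and Acox1 at 3.90. No oxidative phosphorylation gene of 21 met the counting rule, with a median of 1.32 (percentile 99.97). Of 26 cell cycle genes 23 were lower (median -4.18, percentile 0), of 12 imprinted genes 9 (-4.85, percentile 0), of 10 fetal growth genes 6 (-3.65, percentile 0), of 16 stroma genes 11 (-4.14, percentile 0) and of 18 endothelium genes 5 (-2.71, percentile 0). The stroma list averaged 4.18 log2 units in the E15.5 libraries and 0.434 in the adult one. Other cells in the embryonic sort cannot be told apart from age here. The median log2 ratio of all genes was -0.64, which median-ratio scaling shifted by 0.36 and quantile normalization by 0.56. For podocytes the median was -0.28 (shifts 0.25 and 0.24) and for mesangial cells -0.26 (shifts 0.17 and 0.20). The list directions given here for adult libraries held under both scalings. Adult kidneys were dissociated with collagenase and trypsin and embryonic ones with trypsin, so that age and dissociation cannot be told apart in any adult comparison. The column headers of the adult podocyte, mesangial and endothelial libraries also carry the names CD2AP and WT, which the E15.5 and the adult proximal tubule columns do not. The mouse line behind these names is not given in the sources used here, and a difference of line or background cannot be told apart from age in those 3 comparisons.

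In podocytes the adult library held 14 of 28 podocyte markers at higher levels. Col4a3, a collagen chain of the mature glomerular basement membrane (chromosome 1: 82583496 to 82718634), was at 546 RPKM in the adult and 3.89 ± 1.08 RPKM at E15.5 (SD, n = 2), a log2 ratio of 6.82, and Col4a4 had 5.02. Nphs2 was at 4388 RPKM against 291 ± 59.5 RPKM (3.92), and Nphs1, which encodes nephrin, had 3.60. Pcp4, the gene with the largest fold change of E15.5 podocytes, was at 2.48 RPKM in the adult (-8.16).

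In podocytes 398 genes were higher in the adult and 583 lower, 14.3% of genes with at least 10 RPKM. Gm20594 was at 2771 RPKM in the adult podocyte library and at 9963 and 8729 RPKM in those of E15.5, so that this comparison also crosses the split of libraries by that transcript. Of 28 podocyte genes 14 were higher (median 2.08, percentile 100), with Sema3g at 5.88 and Thsd7a at 3.82. Clic3 (7.39), C1qtnf1 (7.25), Myom2 (6.91), Htra1 (6.76) and Nupr1 (6.61) also had high ratios. H2-Q6, H2-Q9 and H2-Q8 had ratios of 9.82, 9.13 and 8.41, but are near-identical paralogs whose separate values are uncertain. Of 13 glomerular basement membrane genes 3 were higher and 1 lower, with a median of -1.08 and a mean of 0.31 (percentile 4.14): the laminin gene Lamb2 was at 3.46 and Lamb1 at -3.22. Of 26 cell cycle genes 21 were lower (-3.33, percentile 0), of 10 imprinted genes 6 (-3.08, percentile 0) and of 8 fetal growth genes 5 (-2.56, percentile 0). Mgst1 (-6.25), Scube3 (-6.18), Frem1 (-6.15), Vcan (-6.14), Mdk (-6.01) and Penk (-5.78) were low in the adult. Markers of other cell types were higher beside these, inside and outside the glomerulus: 11 of 19 endothelium genes (median 3.15, percentile 100) and 7 of 16 mesangium genes, with 1 lower (1.94, percentile 100). The urothelium list had a median of 1.94 (percentile 100, none of 11 genes by the rule), the immune list 1.58 (percentile 99.95, 2 of 10 higher) and the collecting duct list 1.14 (percentile 99.9, 1 of 13 higher).

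Mesangial cells are the contractile cells of the glomerular tuft. Of the libraries labelled as such, the adult one held 12 of 16 mesangium and smooth muscle markers at higher levels. The stroma list averaged 5.67 log2 units in the E15.5 library and 2.84 in the adult one, and the mesangium list 3.94 and 6.96. A difference in the cells sorted therefore cannot be told apart from age in this comparison. Agtr1a, the angiotensin II receptor gene (chromosome 13: 30428225 to 30474736), was at 594 RPKM in the adult and 4.01 RPKM at E15.5 (log2 ratio 6.89), and Ren1, which encodes renin, at 104 and 1.54 RPKM (5.37). Gja5, a connexin gene, was at 759 and 0.633 RPKM (8.86), and Itga8, an integrin gene of mesangium, at 667 and 34.6 RPKM (4.23). Col1a1 was at 0.766 RPKM in the adult and 229 RPKM at E15.5 (-7.02).

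In mesangial cells 676 genes were higher in the adult and 867 lower, 21.7% of genes with at least 10 RPKM. Of 16 mesangium genes 12 were higher (median 3.05, percentile 100), with Gata3 at 5.80, Serpine2 at 4.92 and Sfrp2 at 4.84. Ctgf (7.81), Pcp4l1 (7.40), Pcdh12 (6.98), Nt5e (6.89) and Art3 (6.73) also had high ratios. The E15.5 library held cap mesenchyme genes: of 15 such genes 10 were lower in the adult and 1 higher (-3.90, percentile 0), with Six2 at -5.67 and Sall1 at -5.38, and Cited1 was listed at 0 in the adult and at 76.0 RPKM at E15.5. Of 16 stroma genes 11 were lower and 2 higher (-3.69, percentile 0), of 26 cell cycle genes 22 were lower (-3.74, percentile 0), all 12 imprinted genes were lower (-4.45, percentile 0) and of 9 fetal growth genes 6 were lower (-2.90, percentile 0). Of 13 glomerular basement membrane genes 4 were higher (1.17, percentile 99.92), and of 14 endothelium genes 5 were higher and 1 lower (1.44, percentile 100).

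In endothelial cells the adult library held more Ehd3, a gene of glomerular endothelium (chromosome 17: 74154181 to 74181433), at 1191 RPKM against 57.4 RPKM at E15.5 (log2 ratio 4.35), and less Plvap, of endothelial diaphragms, at 2.79 against 143 RPKM (-5.25). Igfbp5 was at 2443 and 26.4 RPKM (6.48) and Pi16 at 438 and 0.932 RPKM (7.83). Cd300lg (7.01), the small heat shock protein gene Hspb1 (7.00), Nostrin (6.89) and Fgf1 (6.61) followed. Hspa1a (7.07) and Hspa1b (6.79) are near-identical paralogs and uncertain one by one.

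In endothelial cells 367 genes were higher in the adult and 541 lower, 13.4% of genes with at least 10 RPKM. Of 20 endothelium genes 3 were higher and 2 lower (median 0.46, percentile 99.5), Emcn and Eng at 2.32 and 2.21 and Cldn5 at -2.39. Of 26 cell cycle genes 23 were lower (-3.67, percentile 0), of 11 imprinted genes 7 (-3.89, percentile 0) and of 9 fetal growth genes 4 (-1.92, percentile 0). The oxidative phosphorylation list had a median of -1.37 (percentile 0.17). Of other cell types, the immune list had a median of 2.06 (percentile 100, 1 of 10 genes higher) and the mesangium list 1.08 (percentile 99.54, 1 of 8 lower).

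Across all 4 adult lineages 11 genes were higher in each and 142 lower in each, of 9892 genes with at least 10 RPKM in any of these libraries. Independent lists would share 0.0629 and 0.283. Within 1 lineage only 6784 to 7220 genes reached that level, so that some excess over these figures is built in. Fgf1 had log2 ratios of 4.21, 4.60, 4.92 and 6.61 in proximal tubules, podocytes, mesangial and endothelial cells, and the nuclear RNA Neat1 4.37, 4.80, 4.89 and 3.49. Plscr2, Lgals3bp, Lpl, Lims2, Klf9, Mapt, Zbtb20 and Tns1 were among the rest. The shared lower genes included Igf2 (-9.11, -9.10, -8.77 and -8.18), H19 (-9.29, -8.49, -8.85 and -7.50), Mest (-8.39, -5.31, -7.24 and -4.84), the histone gene Hist1h1b (-6.76, -5.28, -5.74 and -5.47) and Ccnb1 (-6.20, -5.53, -4.98 and -5.58), as well as Rrm2, Ube2c, Cks1b and Uhrf1. Age and dissociation go together in all 4, as do the CD2AP and WT headers in 3, and part of the sharing can come from that.

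**Figure D3:**
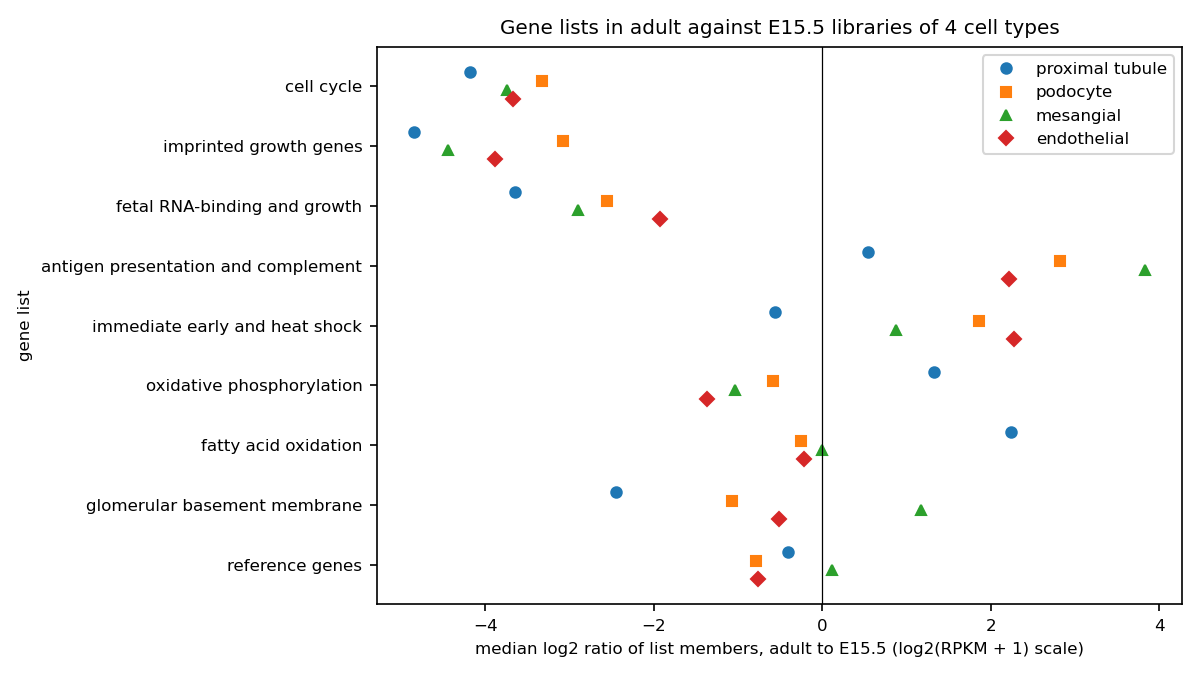
Median log2 ratio of adult to E15.5 libraries for 9 gene lists in 4 lineages, with the ratio on the axis and 1 mark per lineage. The cell cycle list lies at -4.18, -3.33, -3.74 and -3.67 in proximal tubules, podocytes, mesangial and endothelial cells, and fatty acid oxidation at 2.23 in proximal tubules, while the sign turns under another scaling for fatty acid oxidation in podocytes and mesangial cells and, in proximal tubules, for immediate early genes and reference genes.

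The E11.5 ureteric tip and trunk, the first branch of the ureteric bud and its stalk, differed in few genes. Crabp1, a retinoic acid binding protein gene (chromosome 9: 54612615 to 54620916), was at 24.6 RPKM in the tip and 1.50 RPKM in the trunk (log2 ratio 3.35), and Cys1 at 0.487 and 13.7 RPKM (-3.30). Genes met the counting rule in 20 cases for the tip and 12 for the trunk, 0.480% of genes with at least 10 RPKM. No ureteric tip gene of 15 met it (median -0.08, percentile 22.9), with Slco4c1 at 1.10, Cxcr4 at 0.68 and Sox9 at -0.79. Of 15 collecting duct genes 2 were lower in the tip (median -1.04, percentile 0), among them Tfcp2l1 (-2.10), with Tacstd2 at -2.23, and Wnt9b at -1.75 and Gata3 at -1.31 under the rule. The cell cycle inhibitor gene Cdkn1a was at -2.38. Endothelial markers were higher in the tip, 3 of 19 by the rule (median 1.68, percentile 100), with Erg at 2.60, Sox18 at 2.34 and Eng at 2.23. Lmo2 (2.59) and Ecscr (2.38) were also higher in the tip. The cap mesenchyme list had a median of 0.81 (percentile 100) and the stroma list 0.80 (percentile 99.97).

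Between the P4 renal vesicle and the P1 cap mesenchyme, both sorted by the Crym reporter, genes of the forming nephron were higher and progenitor genes lower. Lhx1, a transcription factor of the renal vesicle (chromosome 11: 84332881 to 84339036), was at 158 RPKM in the P4 library and 7.73 RPKM in the P1 library (log2 ratio 4.19), and Hnf1b at 184 and 4.75 RPKM (5.01). Six2, which maintains nephron progenitors (chromosome 17: 86083608 to 86087594), was at 12.7 and 199.6 RPKM (-3.87), and Cited1 at 7.99 and 479.7 RPKM (-5.74). Crym itself was at -6.02.

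The P4 library had 160 genes higher and 82 lower than the P1 library, 3.29% of genes with at least 10 RPKM. Of 15 renal vesicle genes 11 were higher (median 3.04, percentile 100), with Dkk1 at 4.17, the Notch ligands Jag1 at 4.13 and Dll1 at 3.20, and Ccnd1 at 3.48. Emx2 (5.78), Osr2 (4.84), Pou3f3 (4.48), Lama1 (4.37) and Hes5 (4.31) were also high. Of 14 cap mesenchyme genes 7 were lower (-2.16, percentile 0), with Meox1 at -4.44, Gdnf at -3.38 and Eya1 at -3.19. Of 27 podocyte genes 3 were higher and 1 lower (0.58, percentile 100), Mafb at 3.62, Podxl at 2.56 and Robo2 at -3.28. The cell cycle list had a median of 1.16 (percentile 100). Xist was at 0.685 RPKM in the P4 and 108 RPKM in the P1 library (-6.01), and the Y-linked gene Ddx3y at 16.9 and 13.8 RPKM.

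The E12.5 cap mesenchyme, sorted by Six2, and the P1 cap mesenchyme, sorted by Crym, both held the progenitor gene Six2, at 175 and 199.6 RPKM, while Cited1 stood at 48.5 and 479.7 RPKM (log2 ratio -3.28). Of 14 cap mesenchyme genes 1 was lower at E12.5 (median -0.80, percentile 0). Fetal growth genes were higher at E12.5 by their median (1.24, percentile 100), but only 1 of 10 met the rule. This was Hmga1 at 2.04, whose value is uncertain, since its copy Hmga1-rs1 is among the genes with near-identical copies given below. Hmga2 was at 258 and 77.1 RPKM (1.73). Of 26 cell cycle genes 2 were higher (0.90, percentile 100), of 13 immediate early genes 5 were lower (-1.72, percentile 0), and the renal vesicle list had a median of 0.48 (percentile 99.95), with Tmem100 at -2.42. At E12.5 140 genes were higher and 162 lower, 4.21% of genes with at least 10 RPKM. The median of all genes was -0.31 (shifted by 0.20 and 0.24 under the scalings). Gm20594 was at 8254 RPKM in the E12.5 and 1515 RPKM in the P1 library. The 2 libraries also differ in mouse strain, and Y-linked transcripts were nearly absent in the E12.5 but not in the P1 library. Age therefore cannot be told apart from reporter, strain or sex in this comparison.

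Many of the largest differences between these 2 libraries lie in genes with near-identical copies and are uncertain. Gapdh was at 2087 RPKM at E12.5 and 21.7 RPKM in the P1 library (6.52), and Rps2 at 510 and 4.25 RPKM (6.61), with Rpl29, Rpl21 and Rpl7a at 5.35, 5.27 and 5.25. The pseudogenes Eif4a-ps4 and Pgam1-ps2 were at -7.76 and -6.82 and Hmga1-rs1 at -6.25. Gapdh was at 32.0 RPKM in the other Crym library and between 161 and 3019 RPKM in the other 18 libraries.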

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

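The lists below were chosen for the comparison of adult lineages after the medians were seen, with the limit of 0.5 log2 units on each side. Each list had a median log2 ratio of adult to E15.5 above 0.5 in 1 lineage and below -0.5 in another, against every E15.5 library, and the differences between lineages were not tested. The difference of medians was 5.87 for endothelium and 4.85 for erythroid genes, between podocytes and proximal tubules. It was 3.43 for podocyte, 3.00 for urothelium, 2.52 for collecting duct and 2.49 for loop of Henle genes between the same lineages. Between mesangial cells and proximal tubules it was 5.86 for mesangium and 3.61 for glomerular basement membrane genes. Between endothelial cells and proximal tubules it was 5.47 for stroma, 3.46 for immune, 3.13 for ureteric tip and 2.89 for renal vesicle genes. Proximal tubules exceeded mesangial cells by 5.46 for proximal tubule genes and endothelial cells by 2.70 for oxidative phosphorylation genes. The 2 medians of a difference do not cover the same members: endothelial cells and proximal tubules had 5 and 16 measured stroma genes, 7 and 13 ureteric tip genes and 8 and 15 renal vesicle genes, and mesangial cells and proximal tubules 9 and 37 proximal tubule genes. In most of these the lower side is the proximal tubule lineage, whose median over all genes was -0.64. The stroma, erythroid and endothelium lists averaged 4.18, 3.34 and 2.76 log2 units in its E15.5 libraries. In its adult library they averaged 0.434, 0.525 and 0.166. Other cells in the embryonic sort therefore cannot be told apart from age in these differences.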

How the results depend on the processing

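The library family term and the fit of high-Gm20594 libraries were chosen after the result was seen, as was leaving out libraries for lists. Of the counts under alternatives 242 stayed within 1.5 times the main count and 86 did not, and the cause was not tested unless given here. Of the values of named tested genes 3533 kept their direction and side of the threshold, 171 lost the call and 19 gained one. Of the values of named genes without a test 764 stayed within 0.5 log2 units and 460, from 250 of 306 ratios, moved further without a called one changing sign: 228 with a pseudocount of 5, 151 with 0.1 and 81 with quantile normalization. Where 1 side is at a few RPKM or less, the size of such a ratio rests on the pseudocount. Of the list values 1531 kept their direction and side, 87 lost the call, 61 gained one and 1 passed with a mean of the other sign. Depth limits the P1, P4 and proximal tubule 3 libraries most. Deviations from group means correlated at 0.667 between collecting duct 1 and ureter 1 and 0.586 between collecting duct 2 and ureter 2. For the other shared numbers they correlated between -0.0163 and 0.0958. Collecting duct 3 and ureter 2, which share no number, were at 0.521. Deviations in a group of 2 libraries mirror each other, so that these values are not independent and cannot decide whether replicate numbers pair the samples. With the replicate block genes higher and lower numbered 984 and 1307 in podocytes, 887 and 497 in proximal tubules, 700 and 851 in collecting ducts, 1082 and 729 in ureters and 597 and 992 between collecting ducts and ureters, and 65 list tests passed.

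A pseudocount of 5 shrinks low genes by construction and gave 504 and 488 genes in podocytes, 352 and 115 in proximal tubules, 262 and 257 in collecting ducts, 533 and 269 in ureters and 212 and 433 between collecting ducts and ureters. In the adult comparisons it gave 445 lower genes in proximal tubules, 240 and 250 in podocytes, 443 and 487 in mesangial cells and 194 and 310 in endothelial cells, then 2 and 0 for tip and trunk, 83 and 38 for P4 and P1 and 90 and 85 for E12.5 and P1. With only the groups compared, lower genes in podocytes were 432, and counts were 378 and 26 in proximal tubules, 177 and 66 in collecting ducts, 338 and 65 in ureters and 252 and 247 between collecting ducts and ureters. Passing against each other group separately asks for more, and gave 506 and 262, 374 and 25, 181 and 51, and 376 and 95 in podocytes, proximal tubules, collecting ducts and ureters. For proximal tubules a filter of 5 RPKM, which tests fewer genes, gave 515 higher genes, and lower genes were 481 with quantile normalization, 509 with the library family term and 511 with high-Gm20594 libraries only. With the estimated correlation 0 of 120 list tests passed, against 60.

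A log2 ratio of 3 asks for more and gave 340 and 576 genes in adult proximal tubules, 182 and 223 in podocytes, 369 and 403 in mesangial cells, 154 and 241 in endothelial cells, 3 and 1 for tip and trunk, 68 and 33 for P4 and P1 and 76 and 80 for E12.5 and P1. Without a minimum RPKM 1511 genes were lower in adult proximal tubules, and counts were 53 and 35 for tip and trunk, 242 and 138 for P4 and P1 and 214 and 330 for E12.5 and P1. For tip and trunk a pseudocount of 0.1 gave 35 and 23 and a minimum of 5 RPKM gave 38 and 25.

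Leaving out 1 library at a time gave 505 to 1019 higher and 466 to 1271 lower genes in podocytes, 415 to 893 and 72 to 403 in proximal tubules, 480 to 707 and 564 to 959 in collecting ducts, 787 to 1128 and 519 to 904 in ureters, 299 to 666 and 345 to 977 between collecting ducts and ureters, and 57 to 66 list tests. A group left with 1 library is then assumed to vary like the others. In the adult comparisons it gave 651 to 788 and 1086 to 1200 in proximal tubules and 413 to 457 and 583 to 684 in podocytes. The oxidative phosphorylation list in ureters did not pass with all libraries (mean 0.02, median -0.10, adjusted p = 0.804, where the direction of the test was already down). It passed without ureter 1 with a mean of -0.32 (adjusted p = 0.0176), and the mean reached 0.36 without ureter 2.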

Other observations

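The tests of endothelial RNA in ureters, of the library family and of pseudogene reads were chosen after the result was seen, and the interval used for both tests of cell admixture was added once the stromal result was known.

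Genes of antigen presentation were higher in 3 adult lineages, in values without a test. Of the list 9 of 12 genes were higher in adult mesangial cells (median log2 ratio 3.83, percentile 100), 7 of 13 in podocytes (2.83, percentile 100) and 6 of 12 in endothelial cells (2.21, percentile 100), while in proximal tubules 1 was higher and 1 lower of 11 (0.54, percentile 99.1). The adult columns of these 3 lineages carry CD2AP and WT in their headers and that of proximal tubules does not, so that mouse line or background goes with this difference between lineages and stays open beside age and dissociation. The immune list followed this only in part: its median was 2.06 in endothelial cells (1 of 10 genes higher, percentile 100) and 1.58 in podocytes (2 of 10, percentile 99.95), but 0.58 in mesangial cells (0 of 10, percentile 97.4, inside the central 95% of random lists) and -1.40 in proximal tubules (2 of 10 higher, percentile 8.09). Whether immune cells in the sorts contribute was not tested. Ifitm3, an interferon-induced gene, was at 3801 RPKM in adult mesangial cells and 137 RPKM at E15.5 (4.79), but at 4.98 RPKM in adult proximal tubules, with a log2 ratio of -3.67 to E15.5. Immediate early and heat shock genes had medians of 2.28 in endothelial cells, 1.86 in podocytes and 0.88 in mesangial cells, and -0.56 in proximal tubules, where quantile normalization turns the sign (0.23). Sex-linked genes showed Xist with Y-linked genes at no more than 0.0583 RPKM in adult proximal tubules, E12.5 cap mesenchyme and adult endothelial cells. The reverse, Xist at no more than 1.02 RPKM with Y-linked Ddx3y above 5 RPKM, held in both E11.5 libraries, the P4 library and adult podocytes. The adult mesangial library, described as the kidneys of 1 mouse, held Xist at 42.5 and Ddx3y at 5.19 RPKM.

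Endothelial transcripts stood high in the ureter libraries, although the sort was by a Hoxb7 reporter that would remove endothelial cells. Over 35 transcripts with at least 20 RPKM in the E15.5 endothelial library and at most 1 RPKM in collecting duct 2 and 3 and both podocyte libraries, the ureters stood at a median ratio of 0.421 (middle 50% 0.318 to 0.537), and 0% of them fell below 1/8 of that ratio (exact 95% interval up to 10.0%). Of the marker list 18 of 19 genes rose, and Cdh5 and Aplnr were at 266 and 331 RPKM. A term for the library family left the list at a mean of 2.60 log2 units, which argues against the family as the whole cause. Endothelial cells or their RNA in the sort is a candidate explanation, and a difference of the ureter tissue itself stays open and untested.

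Collecting duct 1 and ureter 1 stood apart in Gm20594 from their replicates and from the other libraries of the 4 replicated E15.5 groups. Groups with 1 library lay at no more than 2771 RPKM, except adult proximal tubules at 26726 RPKM and the E12.5 cap mesenchyme at 8254 RPKM. E15.5 mesangial and endothelial cells were thus also low, at 2119 and 2088 RPKM. Across genes the differences went with exon length at Spearman rho -0.223 in collecting duct 1 and -0.199 in ureter 1, with lengths for 90.0% of genes, and genes are not independent replicates. These lie between the bounds of 0.1 and 0.3 set for the test, so that length bias cannot be told apart from other causes. Collecting duct 1 was taken from a collecting duct region and the others from cortical regions per the labels, a biological difference that stays open. The 20 endothelium genes stood in collecting duct 1 at a median of 0.158 of their E15.5 endothelial level (range 0.118 to 0.226). The medians were 0.0121 in collecting duct 2 and 0.0203 in collecting duct 3. Whether endothelial cells or their RNA in that sort set collecting duct 1 apart was not tested. Of 84 splits of the 9 libraries into 3 and 6 in a 2-group fit, 3 gave at least the 243 calls of the collecting ducts, themselves included. The highest other, 377, set proximal tubule 3 and both podocyte libraries apart, and 261 set collecting duct 1 and both ureters apart, for reasons that were not tested. The share is under the 0.05 set beforehand. The splits regroup compartments that differ from each other, and this fit is not the model behind the reported counts. No conclusion on chance is drawn from the share.

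The 2 Crym libraries stood apart in Gapdh, in some ribosomal protein genes and in pseudogenes. Over 380 pairs of a gene and a pseudogene named after it, the lower of the 2 Crym libraries had a median log2 ratio of -5.87 and the highest other library -6.07, a gap of 0.197. The test asked for a gap above 1 for reads given to different copies and for a gap below 0 against it, so that this cause cannot be told apart from others. Mir682, chosen after its values were seen, was at 1370 and 1110 RPKM in these libraries and at no more than 29.2 RPKM elsewhere. Their shared reporter and postnatal age stay open as biological differences, untested.

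Stromal transcripts in proximal tubules were put to the same test as the endothelial ones: of 4 transcripts 25% (exact 95% interval 0.631 to 80.6%) fell below 1/8 of the median ratio of 0.113, too few to decide.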
